A study of Mus musculus and Anolis carolinensis with 24 samples.

How the data were processed

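RNA was sequenced from limb buds, external genitalia and tailbuds of mouse and green anole embryos, with 24 libraries in 12 groups of 2. Per the labels, the authors isolated RNA with a PicoPure kit, enriched mRNA, amplified cDNA by SPIA and made libraries with an Ovation Ultralow kit. The values are estimated counts per gene as deposited by the authors, not scaled for depth or length. The authors' notes name the mouse build mm9 for all samples, and the aligner, the counting tool and the lizard build are not given in the sources used here. The mouse table holds 21590 genes and that of the anole 22635, of which 11710 carry a symbol and 302 symbols lie on more than 1 row. Of the values, 81.3% were whole in the mouse and 59.2% in the anole (tolerance 1e-09), and all were rounded before testing.

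The test was edgeR 4.0.16 (quasi-likelihood) with limma 3.58.1 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15), 1 fit per species over all groups and Benjamini-Hochberg adjustment at 0.05. It covered 14510 mouse and 16467 anole genes. The common biological coefficient of variation was 0.356 and 0.413, with 4 and 6 residual degrees of freedom. The samples, comparisons, named-gene rule, gene lists and most alternatives were fixed before the data were examined. Total counts per library set the precision: 3 counts over a group was the floor for a fold against a group with no count, and ratios over 1 to 3 counts carry an exact binomial interval for counting error alone.

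Replicates were checked with a chi-square test on genes with at least 20 counts in the pair. A ratio to degrees of freedom under 1.5 counted as near-identical, which held for both mouse hindlimb pairs. These were summed, so the mouse fit has 10 samples. The planned fit had all 12 as separate samples with 6 residual degrees of freedom. The change was settled after the data, with both sets of counts known, and the planned counts are given beside the others. Whether a near-identical pair is 1 library sequenced in 2 parts is not given in the sources used here. Replicate numbers did not pair samples across groups.

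In each species 7 comparisons were made: genital tissue against hindlimb at a shared stage, genital tissue and early hindlimb against tailbud, genital tissue and hindlimb over time, the difference between these time changes, and forelimb against early hindlimb. Between species, 10013 symbols matched once in each, and 8412 were tested in both for an interaction. Symbols were capitalised in both tables, and list genes on more than 1 anole row were left out of list tests. The axis used genes past the threshold with an absolute log2 fold of at least 1 between limb buds and tailbud, with log2 CPM at a prior count of 2. Axis and similarity values were compared by exact permutation of 4 against 4 libraries. Named genes were the 6 with the largest rise and the 6 with the largest fall in each comparison (adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between libraries), up to 4 passing members of at most 8 lists by camera p, and 10 regulators named in every comparison. The interaction named 6 genes of each sign. Some genes that this rule names are not reported here. Lists were 22 sets with at least 4 tested genes, tested by camera with a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over all lists and comparisons of a species.

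Alternatives were DESeq2 1.42.0 size factors and Wald test, no filter, a CPM filter, only the groups compared, a replicate block, a minimum log2 fold of 1, thinning to the smallest library, other axis genes and references, and leaving out each library. An offset for gene length (not for axis or similarity), omitting sex-linked genes and settings for genes called in both species came after the data. On simulated data with the same-stage design, 4-fold changes were called for 32 of 67 genes in the mouse and 33 of 67 in the anole, 8-fold changes for 49 of 66 and 41 of 66, and 2-fold changes for 4 of 67 in each, with 3 and 4 unchanged genes called. For the species interaction 2 of 42 were called at 2-fold, and the rest are given below.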

Results

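RNA was sequenced from embryonic tissues of the mouse (strain C57BL/6N) and of the green anole, a lizard. Developing external genitalia were compared with limb buds and with the tailbud, the growing tip of the embryo. The mouse forms a single genital tubercle, and the anole forms paired hemipenes. Each species had 6 groups of 2 libraries. The mouse groups were tailbud and forelimb bud at E9.5, hindlimb bud at E10.0 and E11.5, and genital tubercle at E11.5 and E13.0. The anole groups were tailbud, forelimb bud and hindlimb bud at stage 3, hindlimb bud and hemipenis at stage 5, and hemipenis at stage 9. Total estimated counts per library ran from 9.74 to 13.1 M in the mouse and from 8.12 to 19.5 M in the anole. Levels below are means in library-scaled counts (CPM) ± SD with n = 2 libraries, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

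The 2 libraries of mouse hindlimb E11.5 and the 2 of hindlimb E10.0 were nearly the same, with a chi-square per degree of freedom of 1.33 and 1.21 between their counts, against 16.5 to 63.5 in the other 10 pairs of the series. Each of these 2 pairs was summed and counted as 1 sample, so mouse hindlimb levels have n = 1 and no SD, and the lone sample is assumed to vary like the other groups. This choice was made after the data were seen and departs from the planned fit, and the mouse counts with all 12 libraries counted separately stand beside each result. Nothing in the labels says that the libraries of a group came from separate litters or clutches, so the p-values measure only the spread between these libraries.

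The first comparison asked how genital tissue differs from hindlimb at a shared stage. In the mouse at E11.5, TBX5, a T-box transcription factor best known from the forelimb, was at 86.8 ± 41.2 CPM in the genital tubercle and 0.568 CPM in the hindlimb, a 151-fold difference (log2 fold change 7.24, SE 0.683, adjusted p = 0.0025). SHH, a hedgehog ligand made by the cloacal endoderm and by the posterior limb, was at 137 ± 51.4 against 2.03 CPM (adjusted p = 0.026). The endodermal transcription factor FOXA1 (52.4 ± 11.8 CPM) and the mesenchymal factors FOXF2 (54 ± 1.58 CPM) and TCF21 (47.5 ± 11.6 CPM) had 2 counts or none in the summed hindlimb sample. In the opposite direction, the LIM homeobox genes LHX2 and LHX9 of the distal limb bud stood at 62.4 and 73.6 CPM in the hindlimb and at 0.0723 ± 0.102 and 0.682 ± 0.76 CPM in the genital tubercle. SHOX2, a regulator of proximal limb growth, was at 71.8 against 0.292 ± 0.0989 CPM, and DCX, a microtubule protein known from young neurons, was at 137 against 0.508 ± 0.406 CPM (adjusted p = 0.00057).

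FOXF2 was at least 441-fold higher in the mouse genital tubercle, taking a floor of 3 counts over the hindlimb. AVPR1A, a vasopressin receptor, was at least 107-fold higher and the carboxypeptidase gene CPN1 at least 60.7-fold higher, while the tendon factor SCX was at least 62.8-fold lower. FOXA1 was higher by a ratio of 624 with a counting interval of 172 to 5160, and LHX2 was lower by a ratio of 714 (197 to 5900). The hindlimb gene TBX4 was at 69.2 ± 7.47 CPM in the genital tubercle and 64.9 CPM in the hindlimb (adjusted p = 0.98), and HAND2 at 71.3 ± 30.8 and 62.2 CPM. PITX1 was at 5.55 ± 4.72 and 31.1 CPM (adjusted p = 0.16) and the LIM homeobox gene ISL1 at 489 ± 8.3 and 15.3 CPM (adjusted p = 0.059). HOXD13 was at 1350 ± 605 and 243 CPM (adjusted p = 0.09) and HOXA13 at 300 ± 106 and 52.4 CPM (adjusted p = 0.13).

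By gene lists, 3 of the 15 tested apical ectodermal ridge genes were lower in the mouse genital tubercle and none was higher, or 9 lower and 1 higher adjusted over the list alone. Camera on ridge genes gave adjusted p = 4.3e-09, or 0.11 with an estimated correlation. The 3 were FGF4 (0.0723 ± 0.102 against 12.5 CPM), FGF17 (0 against 1.54 CPM) and DLX1 (5.66 ± 0.139 against 27.5 CPM). The ridge is surface ectoderm, and the surface epithelium list was lower too (median log2 fold change −0.487, 6 of 22 positive, none past the test in either count, camera adjusted p = 0.024, adjusted p = 0.34 with an estimated correlation). Of the 26 external genital outgrowth genes, 4 were higher, including SIX2 at 95.1 ± 5.18 against 6.09 CPM and NR2F1 at 28.1 ± 4.81 against 2.15 CPM, and 1 was lower, with 13 and 2 adjusted over the list alone (camera adjusted p = 5.3e-08). The lower gene was TBX18 at 0.672 ± 0.48 against 83.4 CPM. List calls given with 1 camera p, here and below, also hold with an estimated correlation, 14 in the mouse and 6 in the anole. Cloacal and gut endoderm genes were higher in 4 of 17 cases, FOXA1, SHH and GATA6 (20.6 ± 1.23 against 0.406 CPM) among them, and 5 were higher and 1 lower adjusted over the list alone. For the endoderm list camera gave adjusted p = 6e-05, or 0.21 with an estimated correlation. Endothelial genes rose as a list with 1 of 18 members past the gene test, the lymphatic receptor FLT4 (65.5 ± 0.0529 against 10.3 CPM), and 4 adjusted over the list alone. Camera on endothelial genes gave adjusted p = 0.00032, or 0.23 with an estimated correlation. The gonad and nephric list was higher with 2 of 11 past the test, RET (13.1 ± 5.77 against 0.446 CPM) among them, and 5 higher and 1 lower adjusted over the list alone. Camera on this list gave adjusted p = 0.00052, or 0.27 with an estimated correlation. The steroid hormone list was higher, with 1 of 11 past the test and 2 adjusted over the list alone. Camera on steroid genes gave adjusted p = 0.0076, or 0.17 with an estimated correlation. XIST, the transcript of the inactive X chromosome, was at 8.11 ± 0.435 against 46.9 CPM (adjusted p = 0.011), 1 of 5 in the sex-linked list, which was lower, and 1 adjusted over the list alone. For the sex-linked list camera gave adjusted p = 0.0021, or 0.2 with an estimated correlation. The limb identity list was higher, with TBX5 past the test among 5, 4 of them positive, and 2 higher and 1 lower adjusted over the list alone. Camera on limb identity genes gave adjusted p = 0.012, or 0.17 with an estimated correlation.

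In all, 174 of 14510 mouse genes passed the test, 107 higher and 67 lower in the genital tubercle. With the 12 libraries counted separately 981 were higher and 890 lower. Of the 24 named genes past the threshold, 19 kept it without any 1 library and 11 under every setting run, among them FOXF2, FOXA1, TCF21, LHX2, LHX9, SHOX2, DCX, TBX5, TBX18 and SIX2. Leaving out 1 mouse hindlimb library took away only part of a near-identical pair, here and below, and did not test that arm. The count was 588 with DESeq2's Wald test and 46 with a minimum log2 fold of 1, and against the hindlimb of the earlier stage GATA6 and XIST changed sign.

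In the anole at stage 5, GATA6 was at 83.1 ± 73 against 0.304 ± 0.247 CPM, GATA5 at 139 ± 106 against 0.974 ± 1.1 CPM, and GATA4 at 16.2 ± 17 CPM with no count in the hindlimb, at least 165-fold higher (adjusted p = 0.0052, 0.041 and 0.03). GATA6 was at 135 CPM in replicate 1 and 31.5 CPM in replicate 2, and without replicate 1 GATA5 and GATA4 did not pass (adjusted p = 0.183 and 0.153). Without hindlimb replicate 1 or 2 none of the 3 passed (adjusted p from 0.0572 to 0.264). Of 10 cloacal and gut endoderm genes 1 was higher, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.098). FGF8, the main signal of the apical ectodermal ridge, had no count in either hemipenis library and 80 ± 9.88 CPM in the hindlimb, at least 722-fold lower (adjusted p = 2.1e-05). SALL1 was at 8.32 ± 5.75 against 218 ± 2.2 CPM and LHX9 at 3.7 ± 3.02 against 84 ± 14.6 CPM (adjusted p = 0.0036 and 0.023). TAGLN, an actin-binding protein of smooth muscle, was at 20.3 ± 14.1 against 0.587 ± 0.266 CPM, and LRRN4, a membrane protein gene, at 41.5 ± 29.4 against 0.45 ± 0.185 CPM. The protocadherin gene PCDH8 was also higher (5.35 ± 0.461 against 0.256 ± 0.0886 CPM). TSPEAR (0.0743 ± 0.0129 against 16.6 ± 6.52 CPM), SCIN (0.0834 ± 0.118 against 12.3 ± 0.989 CPM) and the serotonin receptor HTR5A (0.158 ± 0.131 against 7.52 ± 3.07 CPM) were lower.

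The 2 hemipenis libraries of stage 5 differed by a chi-square per degree of freedom of 63.5, the highest of the 12 pairs by that measure. GATA4 was at 28.2 CPM in replicate 1 and 4.26 CPM in replicate 2, and the row of TBX5 with more counts at 27.8 and 1.59 CPM. The limb mesenchyme gene TBX15, chosen after its values were seen, was at 2.61 CPM in replicate 1 and 125 CPM in replicate 2, against 318 and 297 CPM in the hindlimb libraries of that stage and 80 and 63.7 CPM in the hemipenis libraries of stage 9. TBX5 gave 14.7 ± 18.5 against 0.363 ± 0.4 CPM on that row (adjusted p = 0.11). ISL1 was at 74 ± 8.95 against 9.24 ± 3.29 CPM (adjusted p = 0.059) and TBX4 at 122 ± 35.3 against 32.1 ± 2.51 CPM (adjusted p = 0.31). SHH on its row with more counts was at 5.28 ± 7.11 against 4.16 ± 0.693 CPM (adjusted p = 0.95).

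Among the lists, 3 of 12 apical ectodermal ridge genes were lower in the hemipenis, FGF8, FGF9 (0.883 ± 0.0496 against 15.9 ± 5.55 CPM) and SP6 (16.7 ± 7.04 against 132 ± 4.98 CPM), and 4 adjusted over the list alone (camera adjusted p = 6.5e-15, adjusted p = 0.058 with an estimated correlation). Of 16 limb bud mesenchyme genes 4 were lower, ETV4 (21.9 ± 0.839 against 112 ± 25.1 CPM), LHX9, LHX2 (0.413 ± 0.123 against 5.38 ± 1.62 CPM) and ALX1 (6.93 ± 2.24 against 23.3 ± 6.55 CPM). Of these 16, 8 were lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00043, adjusted p = 0.058 with an estimated correlation). The endothelial list was higher with ESAM (36 ± 6.55 against 11.4 ± 0.529 CPM) and SOX18 (30.9 ± 5.87 against 4.92 ± 0.0753 CPM) past the gene test among 13 and 5 adjusted over the list alone (camera adjusted p = 9.4e-07, adjusted p = 0.073 with an estimated correlation). The smooth muscle list was higher with TAGLN past the test among 7 genes and 4 adjusted over the list alone (camera adjusted p = 0.00038, adjusted p = 0.058 with an estimated correlation). In the hedgehog list GLI2, a transcription factor of the pathway, was at 227 ± 3.56 against 121 ± 8.22 CPM, 1 of 11 higher and 4 adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.066 with an estimated correlation). The limb identity list was higher with none of 4 genes past the test over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0029, adjusted p = 0.074 with an estimated correlation). The tailbud list was lower with 0 of 16 past the test over all genes or adjusted over the list alone (camera adjusted p = 0.0077, adjusted p = 0.11 with an estimated correlation). The muscle list was lower with MET at 23.7 ± 4.53 against 72.7 ± 17.6 CPM, 1 of 19 in either count, over all genes or adjusted over the list alone (camera adjusted p = 0.0093, adjusted p = 0.08 with an estimated correlation).

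In all, 131 of 16467 anole genes passed, 63 higher and 68 lower in the hemipenis. The count was 61 without hemipenis replicate 1, and 37 and 40 without hindlimb replicate 1 and 2, and of the 21 named genes past the threshold 5 kept it without any 1 library and none under every setting run. Fitted on the 4 libraries of these groups alone, edgeR called 0 genes, against 2096 at an unadjusted p under 0.05 and 778 adjusted calls with DESeq2 in the fit of all 12.

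**Figure D1:**
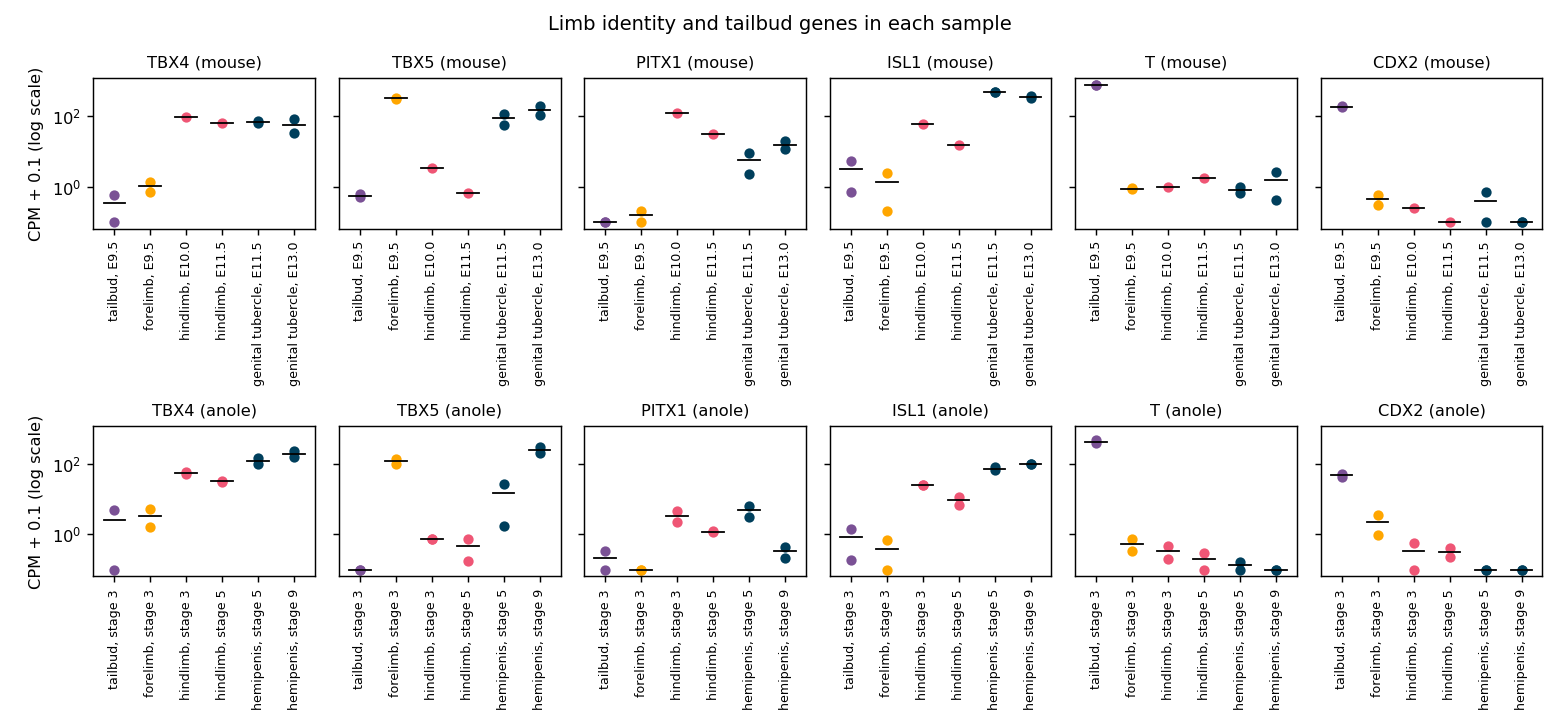
Levels of TBX4, TBX5, PITX1, ISL1, T and CDX2 in every library, as CPM + 0.1 on a log scale, by tissue group and species, with each point 1 library (1 summed pair for mouse hindlimb) and bars at group means. TBX5 lies at 86.8 CPM in mouse genital tubercle and 0.568 CPM in hindlimb at E11.5. T lies at 749 CPM in mouse and 433 CPM in anole tailbud.

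The same-stage differences were then compared between species over 8412 genes matched by symbol. The ridge ligand FGF8 was at 3.26 ± 1.34 CPM in the mouse genital tubercle and 33.2 CPM in the mouse hindlimb, and at 0 and 80 ± 9.88 CPM in the anole (interaction adjusted p = 0.0077). DCX was at 0.508 ± 0.406 against 137 CPM in the mouse but at 47.5 ± 2.02 against 46.6 ± 11 CPM in the anole (log2 difference −7.98, SE 0.569, adjusted p = 4.1e-07). SOST, a Wnt and BMP antagonist, was at 0.6 ± 0.378 against 50.9 CPM in the mouse and at 3.59 ± 1.3 against 2.57 ± 0.535 CPM in the anole (adjusted p = 0.0012). The neural crest genes SOX10 (37.6 ± 4.51 against 0.528 CPM) and NTRK2 (87.8 ± 21.6 against 1.58 CPM) were higher in the mouse genital tubercle. In the anole they were at 1.82 ± 2.39 against 2.87 ± 0.784 CPM and 4.74 ± 5.75 against 7.53 ± 0.516 CPM (interaction adjusted p = 0.035 for SOX10 and 0.042 for NTRK2).

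Genes with a more positive difference in the mouse also included CPN1, PTGS2 and BACE2, and PTGS2, which encodes cyclooxygenase-2, was at 3.73 ± 2.72 against 0 CPM in the mouse and 19.5 ± 13.1 against 13.9 ± 2.27 CPM in the anole (adjusted p = 0.047). Genes with a more positive difference in the anole included DMRT2, a dermomyotome factor at 148 ± 16.1 against 19.6 ± 13.2 CPM in the anole and 0 against 3.08 CPM in the mouse (adjusted p = 0.018). Others were FAM69C (29.2 ± 3.06 against 3.71 ± 1.86 CPM in the anole, 0 against 1.3 CPM in the mouse), WISP1 (3.7 ± 3.81 against 0 CPM in the anole, 4.99 ± 1.42 against 6.9 CPM in the mouse) and TAGLN. The interaction passed for 79 of the 8412 genes, 45 with a more positive difference in the mouse and 34 in the anole. The count was 444 with the 12 mouse libraries counted separately, and on simulated data this test called 13 unchanged genes beside 13 of 42 genes changed 4-fold and 26 of 38 changed 8-fold. It was 33 and 29 without anole hindlimb stage 5 replicate 1 and 2, and 119 without mouse genital tubercle E11.5 replicate 2, and FGF8 and DCX were the named genes past the threshold under every setting run.

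Of the matched genes, 101 passed in the mouse and 87 in the anole, and 10 passed in both, all in the same direction. GATA2, GATA6, the zinc finger factor ZEB2, SVEP1 and the retinol dehydrogenase gene RDH10 were higher in genital tissue in both species, 5 genes against 0.278 expected from independent lists. LHX2, LHX9, ZIC2 and the FGF feedback regulators SPRY2 and DUSP6 were lower in both, 5 genes against 0.234 expected. The overlap was 6 genes without hemipenis replicate 1 and 3 and 4 without anole hindlimb replicate 1 and 2, and ZIC2 alone of the 10 was called in both without any 1 library. Against the earlier hindlimb 22 were called in both, 4 of the 10 among them, and with the 12 libraries counted separately 41, of which 37 had the same direction. SPRY2 was at 5.45 ± 1.38 against 25 CPM in the mouse and 7.83 ± 0.454 against 37.8 ± 0.476 CPM in the anole, and DUSP6 at 28.8 ± 0.519 against 122 CPM and 30.2 ± 4.18 against 164 ± 9.44 CPM. GATA2 was at 30.8 ± 15.6 against 1.26 CPM in the mouse and 66.9 ± 37 against 8.35 ± 2.4 CPM in the anole. Across the 8412 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.145 and a Spearman correlation of 0.177. The Pearson value was 0.416 over the 178 genes past the test in at least 1 species, 0.283 over the 6006 genes with a mean of at least 5 CPM, and 0.0734 without mouse genital tubercle E11.5 replicate 2.

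**Figure D2:**
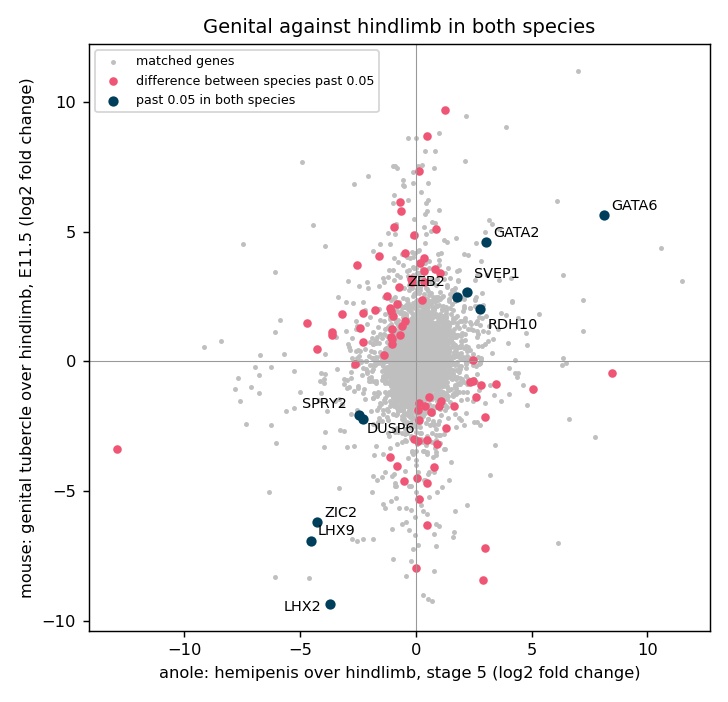
Log2 fold change of genital tissue over hindlimb at the shared stage in the anole (x axis) and the mouse (y axis), with each point 1 of the 8412 symbol-matched genes. The 10 genes past the test in both species lie at the lower left and upper right.

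The next comparisons set genital tissue and hindlimb against the tailbud, the other posterior outgrowth, which was sampled at a younger stage than the genital samples and the mouse hindlimb. In the mouse, the mesoderm regulator T (brachyury) was at 0.711 ± 0.222 CPM in the genital tubercle and 749 ± 8.25 CPM in the tailbud (log2 fold change −9.98, adjusted p = 5.1e-05). The caudal gene CDX2 was at 0.289 ± 0.409 and 183 ± 8.67 CPM (adjusted p = 1e-04). FGF17 (104 ± 23.1 CPM), the presomitic factor MSGN1 (78.3 ± 25 CPM), GAD1 (34.7 ± 15.3 CPM), FGF15 (29.5 ± 4.38 CPM), the Notch ligand DLL3 (25.5 ± 10.7 CPM) and WNT3A (23.1 ± 0.0219 CPM) were found in the tailbud with no count in the genital tubercle. FGF17 was at least 792-fold lower. In the genital tubercle ISL1 was at 489 ± 8.3 against 2.96 ± 3.36 CPM, TBX5 at 86.8 ± 41.2 against 0.454 ± 0.0701 CPM. TBX4 was at 69.2 ± 7.47 against 0.243 ± 0.343 CPM and SHH at 137 ± 51.4 against 0.768 ± 1.09 CPM (adjusted p from 5.3e-05 to 0.00065 over these 4 genes). HOXA13 and HOXD13, which pattern digits and genitalia, were 28-fold and 10.8-fold higher. Of the 10 posterior HoxA and HoxD genes 3 were higher and 4 lower, or 3 and 7 adjusted over the list alone, with a median log2 fold change of −1.29, and the list did not pass (camera adjusted p = 0.07). TCF21, NR2F1, MYBPC1, DPEP1 and CLDN11 were found in the genital tubercle with no count in the tailbud, MYBPC1 at least 551-fold higher.

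Of 24 tailbud and presomitic mesoderm genes, 18 were lower and 2 higher in the mouse genital tubercle, 19 and 3 adjusted over the list alone (camera adjusted p = 1.1e-42). The lower genes included CYP26A1, which degrades retinoic acid (0.819 ± 0.375 against 230 ± 7.98 CPM), NKX1-2 (0.217 ± 0.307 against 330 ± 43.3 CPM) and CDX4 (0.166 ± 0.235 against 283 ± 21.8 CPM). External genital outgrowth genes were higher in 17 of 26 cases and lower in 2, or 19 and 2 adjusted over the list alone (camera adjusted p = 1.9e-23). OSR1 was at 87.2 ± 29.2 against 0.655 ± 0.332 CPM and NR2F2 at 185 ± 11.7 against 6.72 ± 2.39 CPM. Limb bud mesenchyme genes were higher in 18 of 27 cases and lower in 2, or 21 and 4 adjusted over the list alone (camera adjusted p = 1.4e-22). TBX3 was at 800 ± 5.41 against 48.3 ± 3.82 CPM and MEIS2 at 645 ± 38.7 against 46.1 ± 1.01 CPM. Of 12 posterior HoxB and HoxC genes 8 were lower and all 12 were lower adjusted over the list alone (camera adjusted p = 3e-20). HOXC6 was at 5.29 ± 1.76 against 222 ± 35.8 CPM and HOXC10 at 77.9 ± 19.9 against 1000 ± 84.6 CPM. All 5 limb identity genes were higher, also adjusted over the list alone (camera adjusted p = 2.7e-18). Macrophage and white blood cell genes were higher in 6 of 11 cases, with MRC1 at 16.8 ± 2.48 against 0.244 ± 0.227 CPM, and in 7 adjusted over the list alone. Camera on macrophage genes gave adjusted p = 2.3e-06, or 0.075 with an estimated correlation. The hedgehog list was higher in 5 of 11 cases and lower in 1, with the inhibitor HHIP at 33.8 ± 2.77 against 0.902 ± 0.326 CPM and the receptor PTCH1 at 403 ± 64.4 against 126 ± 33.1 CPM, or 6 and 2 adjusted over the list alone. For the hedgehog list camera gave adjusted p = 0.00028, or 0.17 with an estimated correlation. Surface epithelium was higher in 6 of 22 cases, with KRT5 at 38.6 ± 3.25 against 0.809 ± 1.14 CPM and TRP63 at 134 ± 74.4 against 27.4 ± 4.64 CPM, and in 9 adjusted over the list alone. Camera on surface epithelium genes gave adjusted p = 0.00028, or 0.17 with an estimated correlation. In all, 1336 genes passed, 872 higher and 464 lower in the genital tubercle, and with the 12 libraries counted separately 1519 and 1118. Without tailbud replicate 1 or 2 the count was 576 or 593, and of the 46 named genes past the threshold 40 kept it under every setting run.

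Between mouse hindlimb at E10.0 and tailbud, PITX1, the hindlimb identity factor, was at 119 CPM in the hindlimb with no count in the tailbud, at least 962-fold higher (adjusted p = 0.00061). HAND2 was at 75 against 0.0824 ± 0.00215 CPM, TBX4 at 97.6 against 0.243 ± 0.343 CPM and ISL1 at 59.2 against 2.96 ± 3.36 CPM (adjusted p = 0.00011, 0.00042 and 0.019). DCX (25.9 CPM), DPEP1 (15.4 CPM), UPK3B (13.2 CPM), CYGB (12.9 CPM) and MYBPC1 (12.1 CPM) also had no count in the tailbud. T was at 0.844 against 749 ± 8.25 CPM and CDX2 at 0.153 against 183 ± 8.67 CPM. FOXB1 (96.1 ± 16 CPM), BLNK (40.7 ± 4.18 CPM), AVPR1B (23.6 ± 3.47 CPM), WNT3A and the brain factor OTX1 (19.6 ± 0.0113 CPM) were found in the tailbud with no count in the hindlimb. HOXA13 (9.13 against 10.7 ± 6.22 CPM), HOXD13 (65.4 against 125 ± 4.2 CPM) and SHH (2.26 against 0.768 ± 1.09 CPM) did not pass.

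Limb bud mesenchyme genes were higher in 20 of 27 cases and lower in 1, or 22 and 1 adjusted over the list alone (camera adjusted p = 1.5e-42). LHX2 was at 211 against 0.92 ± 1.07 CPM and ALX4 at 192 against 2.37 ± 1.69 CPM. Of 24 tailbud genes 16 were lower and 3 higher, or 17 and 3 adjusted over the list alone (camera adjusted p = 1.2e-29), GREB1 at 53 against 908 ± 155 CPM among them. All 5 limb identity genes were higher, also adjusted over the list alone (camera adjusted p = 1.5e-17). Of 12 posterior HoxB and HoxC genes 6 were lower, with HOXB7 at 4.87 against 101 ± 31.9 CPM, or 10 adjusted over the list alone (camera adjusted p = 1.8e-11). External genital outgrowth genes were higher in 9 of 26 cases, with NR2F2 at 133 CPM, and lower in 2, WNT5A (96.7 against 803 ± 26.5 CPM) and SALL1 (79.2 against 719 ± 84.2 CPM), or 13 and 2 adjusted over the list alone (camera adjusted p = 1.7e-06). Macrophage genes were higher in 2 of 11 cases, MRC1 and C1QB, and in 8 adjusted over the list alone. For the macrophage list camera gave adjusted p = 2.3e-06, or 0.075 with an estimated correlation. Endothelial genes were higher in 3 of 18 cases, ERG (34.4 against 5.43 ± 0.208 CPM), EMCN (79.3 against 14.9 ± 1.07 CPM) and KDR (86.1 against 24.2 ± 1.8 CPM), and 7 adjusted over the list alone. Camera on endothelial genes gave adjusted p = 1.7e-05, or 0.17 with an estimated correlation. The steroid hormone list was lower, with GREB1 past the test among 11, 2 of them positive, and 3 lower adjusted over the list alone. For the steroid list camera gave adjusted p = 0.0013, or 0.12 with an estimated correlation. In all, 630 genes passed, 370 higher and 260 lower in the hindlimb, and with the 12 libraries counted separately 1558 and 1406. Without tailbud replicate 1 or 2 the count was 289 or 259, and of the 37 named genes past the threshold 27 kept it under every setting run.

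In the anole, T was at 0.0326 ± 0.0461 CPM in the stage 5 hemipenis and 433 ± 61.6 CPM in the tailbud (adjusted p = 1.9e-05), and CDX2 had no count against 47.5 ± 8.24 CPM, at least 441-fold lower (adjusted p = 0.0017). FGF8 (182 ± 17.1 CPM), SYT4 (81.7 ± 52.1 CPM), HOXC12 (60.9 ± 4.06 CPM), WNT8A (59.1 ± 0.376 CPM) and FGF3 (56.6 ± 11.9 CPM) were likewise found in the tailbud with no count in the hemipenis. LIX1 (204 ± 42.2 CPM), DMRT2 (148 ± 16.1 CPM) and GATA6 (83.1 ± 73 CPM) had 1 count in the tailbud, and TNXB, GATA4 and TMEM119 had none. ISL1 was at 74 ± 8.95 against 0.727 ± 0.913 CPM, TBX4 at 122 ± 35.3 against 2.41 ± 3.4 CPM and HAND2 at 20.5 ± 17.8 against 0.694 ± 0.981 CPM (adjusted p = 0.00055, 0.0037 and 0.013). SHH on its row with more counts was at 5.28 ± 7.11 against 41.3 ± 9.22 CPM (adjusted p = 0.12), HOXA13 at 5.1 ± 4.14 against 4.39 ± 2.33 CPM and HOXD13 at 6.52 ± 3.79 against 4.42 ± 3.67 CPM.

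Of 9 posterior HoxB and HoxC genes 8 were lower in the hemipenis and all 9 adjusted over the list alone (camera adjusted p = 1.1e-18). HOXB9 was at 67.4 ± 5.7 against 1130 ± 215 CPM and HOXC13 at 0.0417 ± 0.059 against 118 ± 40.7 CPM. Of 16 tailbud genes 10 were lower and 2 higher, or 10 and 3 adjusted over the list alone (camera adjusted p = 1.3e-10). TBX6 was at 0.557 ± 0.511 against 201 ± 1.86 CPM and SALL4 at 198 ± 65.8 against 1230 ± 418 CPM. Of 8 posterior HoxA and HoxD genes 4 were lower, HOXD10 (13.7 ± 3.89 against 244 ± 34.3 CPM), HOXD11, HOXA10 and HOXA11, and 5 adjusted over the list alone. Camera on HoxA and HoxD genes gave adjusted p = 1.1e-06, or 0.077 with an estimated correlation. All 4 tested limb identity genes were higher, also adjusted over the list alone (camera adjusted p = 2.5e-06, adjusted p = 0.058 with an estimated correlation). Of 12 apical ectodermal ridge genes 5 were lower, FGF9 and SP6 (16.7 ± 7.04 against 199 ± 27.9 CPM) among them, or 5 lower and 2 higher adjusted over the list alone. For the ridge list camera gave adjusted p = 8.6e-06 and adjusted p = 0.18 with an estimated correlation. Smooth muscle genes were higher in 3 of 7 cases, with MYOCD, a cofactor of smooth muscle genes, at 122 ± 96.3 against 13.5 ± 11.3 CPM, and in 4 adjusted over the list alone. Camera on smooth muscle genes gave adjusted p = 0.00045, or 0.058 with an estimated correlation. Limb bud mesenchyme genes were higher in 6 of 16 cases, with MEIS1 at 577 ± 9 against 31.8 ± 12 CPM, and lower in 3, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.065 with an estimated correlation). Endothelial genes were higher in 3 of 13, with ERG at 180 ± 15.6 against 8.96 ± 2.05 CPM, and 5 adjusted over the list alone. For the endothelial list camera gave adjusted p = 0.0023, or 0.18 with an estimated correlation. In all, 1941 genes passed, 1090 higher and 851 lower in the hemipenis. The count was 1153 without hemipenis replicate 2 and 1273 without tailbud replicate 2, and of the 41 named genes past the threshold 30 kept it under every setting run.

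Anole hindlimb at stage 3 differed from the tailbud in ALX1 (58.5 ± 4.24 CPM, no count in the tailbud, at least 402-fold higher, adjusted p = 4.2e-05) and TBX15 (266 ± 42 against 0.253 ± 0.127 CPM, adjusted p = 0.0047), both homeobox or T-box factors of limb mesenchyme. FETUB (25.7 ± 26.9 CPM), PRDM16 (15.7 ± 3.17 CPM), LIX1 (67 ± 43.1 CPM) and TNXB (6.44 ± 5.4 CPM) had at most 1 count in the tailbud. TBX4 was at 56 ± 4.24 against 2.41 ± 3.4 CPM, ISL1 at 25 ± 0.0188 against 0.727 ± 0.913 CPM and HAND2 at 17.3 ± 4.81 against 0.694 ± 0.981 CPM (adjusted p = 0.01, 0.0025 and 0.016). T (0.233 ± 0.181 against 433 ± 61.6 CPM), CDX2 (0.232 ± 0.328 against 47.5 ± 8.24 CPM), MSGN1 (0 against 25.1 ± 12.7 CPM), WNT8A, FGF3, HOXC12 and HOXC13 were lower.

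Of 9 posterior HoxB and HoxC genes 6 were lower and 8 adjusted over the list alone (camera adjusted p = 9.9e-16). Of 16 limb bud mesenchyme genes 11 were higher, also 11 adjusted over the list alone (camera adjusted p = 3.1e-12). LHX9 was at 161 ± 23.7 against 1.39 ± 0.345 CPM and MEIS2 at 302 ± 3.25 against 23.3 ± 0.811 CPM. Of 16 tailbud genes 9 were lower and 2 higher, LIN28B at 298 ± 20.8 against 53.5 ± 18.9 CPM being 1 of the higher genes, or 10 and 2 adjusted over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.058 with an estimated correlation). All 4 limb identity genes were higher, also adjusted over the list alone (camera adjusted p = 2.6e-05, adjusted p = 0.058 with an estimated correlation). Cell division genes were higher in 8 of 21 cases, with BUB1 at 593 ± 58.5 against 238 ± 49.8 CPM and MCM5 at 165 ± 11.4 against 44.8 ± 0.0523 CPM, and 9 adjusted over the list alone (camera adjusted p = 0.00038, adjusted p = 0.058 with an estimated correlation). Posterior HoxA and HoxD genes were lower in 3 of 8 cases, HOXD10 (67.3 ± 4.77 CPM), HOXA10 and HOXD11, and 6 adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.2 with an estimated correlation). The smooth muscle and neural lists did not pass (camera adjusted p = 0.057 and 0.093), with SYNPO2 at 77.7 ± 27.1 against 2.16 ± 0.298 CPM and the neural crest receptor ERBB3 at 18.9 ± 6.51 against 82.5 ± 5.5 CPM past the gene test. In all, 2176 genes passed, 1165 higher and 1011 lower in the hindlimb. The count was 818 and 823 without hindlimb replicate 1 and 2 and 1447 without tailbud replicate 2, and of the 36 named genes past the threshold 22 kept it under every setting run.

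Each genital library was placed on an axis from the tailbud mean (0) to the early limb bud mean (1). The axis used 917 genes in the mouse (403 higher in limb, 514 higher in tailbud) and 1341 in the anole (602 and 739). Mouse genital libraries lay at 0.798 ± 0.0132 (n = 4) and anole genital libraries at 0.898 ± 0.0299 (n = 4), a difference of 0.1 (two-sided exact permutation test, p = 0.0286, the smallest that 70 splits allow). The hemipenis libraries lay at 0.905 and 0.938 at stage 5 and at 0.875 and 0.874 at stage 9, and the genital tubercle libraries at 0.813 and 0.787 at E11.5 and at 0.787 and 0.804 at E13.0. Later hindlimb buds, which did not set the axis, lay at 0.862 in the mouse and at 0.877 and 0.899 in the anole. Without anole forelimb replicate 2 the anole mean fell to 0.823 and the difference to 0.025 (exact p = 0.229), and with hindlimb alone as the limb end it was 0.0468 (exact p = 0.0857).

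Without choosing genes, the Spearman correlation of a genital library with early hindlimb minus that with tailbud was 0.0333 ± 0.0149 in the mouse (n = 4) and 0.0579 ± 0.00592 in the anole (n = 4), a difference of 0.0247 (exact permutation p = 0.0286). Over the 1000 most variable genes it reversed to −0.0334 (exact p = 0.371), and against the later hindlimb it was 0.00467 (exact p = 0.6). Leaving out any 1 of the 4 hemipenis libraries gave an exact p of 0.0857, and leaving out anole tailbud replicate 2 gave 0.0571. Species were not replicated, and the 4 libraries of each come from 2 stages and share references, whose error is in no SD or p here. Both tests cover these libraries only.

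**Figure D3:**
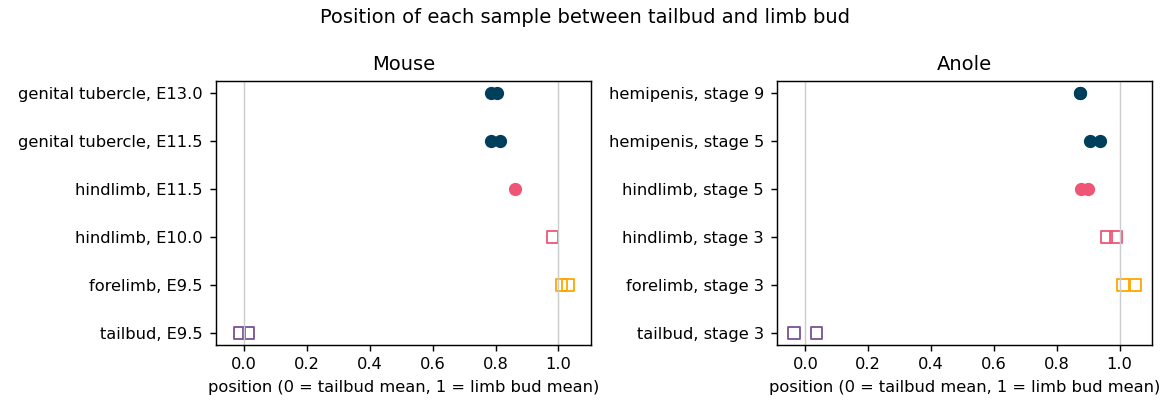
Position of each library on the tailbud-to-limb axis of its species (0 is the tailbud mean, 1 the mean of forelimb and early hindlimb), by group, with each point 1 library or 1 summed pair and open squares for the groups that set the axis. Genital libraries lie at 0.874 to 0.938 in the anole and at 0.787 to 0.813 in the mouse.

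Change with stage was examined within each outgrowth. Sex-linked genes point to female E13.0 genital tubercles in the mouse, so sex goes with stage there. In the mouse genital tubercle between E11.5 and E13.0, XIST was at 5530 ± 365 CPM at E13.0 and 8.11 ± 0.435 CPM at E11.5 (adjusted p = 9.2e-06). The Y-linked genes KDM5D (0.982 ± 0.552 against 142 ± 3.72 CPM), UTY (0.578 ± 0.0186 against 44.8 ± 20.3 CPM), DDX3Y (0.3 ± 0.146 against 35.1 ± 14.6 CPM) and EIF2S3Y (0.121 ± 0.171 against 14.3 ± 4.38 CPM) were lower. KRT5 rose to 659 ± 311 from 38.6 ± 3.25 CPM, KRT14 to 124 ± 40.5 from 8.65 ± 1.26 CPM, ITGB4 to 81 ± 11.7 from 7.79 ± 4.12 CPM and DSP to 696 ± 214 from 175 ± 69 CPM (adjusted p = 0.013, 0.014, 0.0052 and 0.016). Without E13.0 replicate 1 KRT5 and KRT14 did not pass (adjusted p = 0.0605 and 0.0983), nor did KRT14 without E11.5 replicate 1 and DSP without E13.0 replicate 2 (adjusted p = 0.052 and 0.0801). These 4 belong to the surface epithelium list, with 7 of 22 higher, or 13 and 1 lower adjusted over the list alone. Camera on it gave adjusted p = 3e-09, or 0.09 with an estimated correlation. The vascular receptors FLT4 (11.6 ± 2.57 from 65.5 ± 0.0529 CPM) and KDR (10.6 ± 3.41 from 53.1 ± 17.8 CPM) fell (adjusted p = 0.0028 and 0.01), but KDR did not pass without E13.0 replicate 2 (adjusted p = 0.0801). None of the 10 regulators named in every comparison passed, with TBX5 at 150 ± 60.4 against 86.8 ± 41.2 CPM (adjusted p = 0.27), SHH at 28.7 ± 4.11 against 137 ± 51.4 CPM (adjusted p = 0.11) and HOXA13 at 70.5 ± 33.9 against 300 ± 106 CPM (adjusted p = 0.066).

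CYP2W1 (28.4 ± 23.3 CPM), the sodium channel subunit SCN3B (37.7 ± 14.7 CPM), PTPRQ (15.1 ± 0.935 CPM), TRP73 (8.48 ± 3.77 CPM) and HIC1 (7.52 ± 2.83 CPM) rose from 1 or 2 counts at E11.5. SYT6 and CPN1 fell from 9.74 ± 3.15 and 7.46 ± 0.424 CPM to 0.211 ± 0.159 and 0.22 ± 0.0318 CPM. The sex-linked list had all 5 members past the test, 1 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 2.4e-12). Endothelial genes fell in 3 of 18 cases, CDH5 (57.7 ± 11.8 from 157 ± 23.4 CPM) being the third, and 4 adjusted over the list alone. CDH5 did not pass without E13.0 replicate 1 or 2 or E11.5 replicate 2 (adjusted p = 0.143, 0.0801 and 0.0566). Camera on endothelial genes gave adjusted p = 0.00071, or 0.27 with an estimated correlation. Cell division genes fell as a list, with RRM2 at 101 ± 10.5 from 260 ± 24.3 CPM past the gene test among 24 and 7 adjusted over the list alone. Camera on cell division genes gave adjusted p = 0.0014, or 0.27 with an estimated correlation. The neural list rose with DCX (17.9 ± 0.198 from 0.508 ± 0.406 CPM) and STMN2 (25.1 ± 3 from 0.894 ± 0.167 CPM) past the test among 17, and 3 higher and 1 lower adjusted over the list alone. For the neural list camera gave adjusted p = 0.0027, or 0.17 with an estimated correlation. Of 10 posterior HoxA and HoxD genes none passed over all genes and 5 were lower adjusted over the list alone, and 3 had a positive log2 fold change. Camera on HoxA and HoxD genes gave adjusted p = 0.0086, or 0.17 with an estimated correlation. The smooth muscle and external genital lists did not pass (camera adjusted p = 0.07 and 0.072), though TBX18 rose to 14.1 ± 2.04 from 0.672 ± 0.48 CPM and SALL1 and DACH1 were among 3 that fell.

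In all, 272 mouse genes passed, 154 higher and 118 lower at E13.0, and with the 12 libraries counted separately 759 and 738. The count was 78 and 72 without E13.0 replicate 1 and 2, 146 without E11.5 replicate 1, and 263 without the sex-linked list. Of the 26 named genes past the threshold 9 kept it under every setting run, the 5 sex-linked genes with FLT4, ITGB4, DCX and STMN2.

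In the anole hemipenis between stages 5 and 9, the neuronal gene STMN3 rose to 176 ± 1.5 from 1.46 ± 0.409 CPM (adjusted p = 7.6e-05). ADAM22, a synaptic membrane protein, was at 169 ± 37.6 against 2.15 ± 0.269 CPM, and ACTC1, the cardiac and embryonic muscle actin, at 47.3 ± 14.4 against 0.381 ± 0.17 CPM (adjusted p = 0.0025 and 0.015). TBX22 (13.7 ± 6.67 CPM) and the opioid receptor OPRK1 (15.4 ± 7.69 CPM) rose from 1 and 2 counts, and NR0B1 rose to 34.1 ± 0.547 from 0.446 ± 0.0773 CPM. GATA5 (0.677 ± 0.957 from 139 ± 106 CPM), LRRN4 (0.212 ± 0.299 from 41.5 ± 29.4 CPM) and TAGLN (0.26 ± 0.129 from 20.3 ± 14.1 CPM) fell. So did the Wnt agonist RSPO2 (0.176 ± 0.249 from 27.1 ± 0.276 CPM, adjusted p = 0.0012), PRDM6 and C10orf105. TBX5 was at 254 ± 63.7 against 14.7 ± 18.5 CPM on its row with more counts (adjusted p = 0.083) and rose to 25.1 ± 0.527 from 0.586 ± 0.002 CPM on the other (adjusted p = 0.0096).

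The muscle list rose with ACTC1 past the gene test among 19 and 5 adjusted over the list alone (camera adjusted p = 1e-08). Posterior HoxB and HoxC genes fell in 2 of 9 cases, HOXB6 (5.21 ± 0.424 from 98.7 ± 20 CPM) and HOXB9 (8.4 ± 1.77 from 67.4 ± 5.7 CPM), and 4 adjusted over the list alone (camera adjusted p = 8e-07, adjusted p = 0.058 with an estimated correlation). Cell division genes fell as a list, with none of 21 past the test over all genes and 8 adjusted over the list alone (camera adjusted p = 2.2e-06). The smooth muscle list fell, with TAGLN past the test among 7, and 3 adjusted over the list alone (camera adjusted p = 0.00045, adjusted p = 0.058 with an estimated correlation). The hedgehog list fell with CDON at 78.4 ± 10.9 from 258 ± 71.2 CPM, 1 of 11, and 4 adjusted over the list alone (camera adjusted p = 0.00079, adjusted p = 0.058 with an estimated correlation). The tailbud list fell with SALL4 (24.4 ± 2.24 from 198 ± 65.8 CPM) and LIN28B (48.5 ± 8.58 from 186 ± 8.71 CPM), both genes of early progenitors, 2 of 16, and 3 adjusted over the list alone (camera adjusted p = 0.001, adjusted p = 0.07 with an estimated correlation). The neural list rose with ELAVL3 at 4.77 ± 0.441 CPM from no count, at least 43.8-fold, 1 of 11, and 3 adjusted over the list alone (camera adjusted p = 0.0024, adjusted p = 0.07 with an estimated correlation). The cartilage list fell with SOX5 (16.3 ± 7.06 from 106 ± 26.1 CPM), SOX6 (7.35 ± 2.77 from 54.4 ± 20.1 CPM) and SULF2 past the test among 18, and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.2 with an estimated correlation). In all, 259 genes passed, 121 higher and 138 lower at stage 9. The count was 86 and 78 without stage 9 replicate 1 and 2 and 116 without stage 5 replicate 1, and of the 22 named genes past the threshold 7 kept it under every setting run, STMN3, ADAM22, RSPO2, C10orf105, HOXB6, HOXB9 and SALL4.

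Few single genes passed in the hindlimb over time. In the mouse from E10.0 to E11.5, the angiotensin receptor AGTR2 rose to 72.2 from 1.04 CPM, GABRP to 63.8 from 0.997 CPM, LRRN1 to 83.3 from 7.32 CPM and COL12A1 to 58.7 from 6.52 CPM. COL14A1 fell to 1.62 from 30.8 CPM. Each level was 1 summed sample with no spread. Surface epithelium rose as a list, with 0 of 22 members past the test over all genes and 11 adjusted over the list alone (camera adjusted p = 1.7e-15). Limb bud mesenchyme fell, with 8 lower and 2 higher of 27 adjusted over the list alone (camera adjusted p = 9.6e-08, adjusted p = 0.06 with an estimated correlation). Endothelium fell, with 3 lower of 18 adjusted over the list alone. Camera on endothelial genes gave adjusted p = 4.4e-09, or 0.12 with an estimated correlation. Of the lists that follow, no member passed over all genes. The red blood cell list rose, with 0 of 16 adjusted over the list alone (camera adjusted p = 3.6e-08, adjusted p = 0.37 with an estimated correlation). So did the ridge (1 of 15), cartilage (1 of 20) and sex-linked lists (1 of 5). Their camera adjusted p was 0.00025, 0.0019 and 0.0002, and 0.18, 0.12 and 0.17 with an estimated correlation. The limb identity list fell, with 1 of 5 (0.0027, adjusted p = 0.14 with an estimated correlation), with PITX1 at 31.1 against 119 CPM (adjusted p = 0.69). In all, 7 genes passed, 5 higher and 2 lower, and 1016 had an unadjusted p under 0.05, in a comparison of 1 summed sample with 1. With the 12 libraries counted separately 611 genes were higher and 624 lower, DESeq2's Wald test called 193, and with an offset for gene length edgeR called 0.

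In the anole hindlimb from stage 3 to stage 5, EYA4 rose to 14.7 ± 4.42 from 1.4 ± 0.201 CPM, the proteoglycan OGN to 43.5 ± 12.1 from 6.04 ± 3.04 CPM, and DACT1 and PLEKHA7 rose 3.27-fold and 2.91-fold. HOXB9 fell to 22.3 ± 8.37 from 94.7 ± 6.48 CPM and CECR2 to 96.1 ± 3.31 from 231 ± 8.33 CPM (adjusted p from 0.025 to 0.046 over these 6 genes). The posterior HoxB and HoxC list fell, with HOXB9 past the test among 9, and 2 adjusted over the list alone. For the HoxB and HoxC list camera gave adjusted p = 0.00045, or 0.074 with an estimated correlation. The posterior HoxA and HoxD list (3 of 8 lower adjusted over the list alone) and the limb bud mesenchyme list (2 of 16) fell. So did the red blood cell list (0 of 6) and the endothelial list (3 lower and 1 higher of 13). Camera adjusted p was 0.002, 0.0055, 0.0057 and 0.015 in this order, and 0.21, 0.074, 0.32 and 0.28 with an estimated correlation. None had a member past the gene test over all genes. The cartilage (3 of 18 higher), muscle (0 of 19) and surface epithelium lists (0 of 12) rose, likewise with none. Their camera adjusted p was 0.0036, 0.0053 and 0.018, and 0.15, 0.074 and 0.5 with an estimated correlation. In all, 8 genes passed, 5 higher and 3 lower, and 1866 had an unadjusted p under 0.05. The count was 1 and 4 without stage 3 replicate 1 and 2, 4 and 3 without stage 5 replicate 1 and 2, and 433 with DESeq2's Wald test, and none of the 6 named genes kept the threshold without each library in turn.

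The change with stage was tested for a difference between tissues. Genital tissue was followed over later stages than hindlimb, so tissue and stage cannot be told apart. In the mouse, the difference was negative for KDM5D, UTY and DDX3Y and positive for XIST (adjusted p = 0.00097, 0.0052, 0.0063 and 0.0045). Sex at E13.0 may account for these 4. COL14A1, a fibril-associated collagen, was at 37 ± 4.39 CPM at E13.0 and 10.5 ± 0.148 CPM at E11.5 in the genital tubercle and went from 30.8 to 1.62 CPM in the hindlimb (log2 difference 6.05, adjusted p = 0.0052). These 5 genes were the calls, 2 higher and 3 lower, and with the 12 libraries counted separately 120 were higher and 121 lower. The sex-linked list was lower, with 3 of 5 lower and 1 higher, or 4 and 1 adjusted over the list alone (camera adjusted p = 1.9e-23). In the other lists no member passed over all genes, and the counts given are those adjusted over the list alone. The red blood cell list was lower (2 of 16, camera adjusted p = 9.4e-09, adjusted p = 0.35 with an estimated correlation). So were the external genital (6 of 26), posterior HoxA and HoxD (3 of 10) and cartilage lists (1 of 20). Their camera adjusted p was 0.00073, 0.011 and 0.032, and 0.1, 0.17 and 0.18 with an estimated correlation. The limb bud mesenchyme (2 of 27), smooth muscle (1 of 10) and limb identity lists (2 of 5) were higher. For them camera adjusted p was 0.00037, 0.0098 and 0.011, and 0.13, 0.35 and 0.17 with an estimated correlation. Without the sex-linked list 1 gene passed, and without genital tubercle E11.5 replicate 2 the count was 19.

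In the anole, TBX22, STMN3, PCDH8, CCDC85A, ADAM22 and GAP43, the last a growth cone protein at 2970 ± 90.6 CPM in stage 9 and 50.5 ± 26.5 CPM in stage 5 hemipenis, rose more in the hemipenis than in the hindlimb (adjusted p = 0.03, 0.00016, 0.017, 0.0046, 0.026 and 0.026). APOM (0 from 4.5 ± 0.00433 CPM), RSPO2, CDH18, ANGPT1 (1.3 ± 0.677 from 20.9 ± 9.42 CPM), MECOM (43.1 ± 20.7 from 705 ± 221 CPM) and C10orf105 fell more (adjusted p from 0.014 to 0.043). In the limb bud mesenchyme list ALX1 (145 ± 35.4 from 6.93 ± 2.24 CPM in the hemipenis) and ETV4 (98.8 ± 2.19 from 21.9 ± 0.839 CPM) were higher. The list passed upward with a median of −0.085 and a mean of 0.0134 on the log2 scale, with 6 higher and 4 lower of 16 adjusted over the list alone. Camera on limb mesenchyme genes gave adjusted p = 0.02, or 0.11 with an estimated correlation. The cartilage list was lower with SOX5 and SULF2 past the test among 18, and 6 adjusted over the list alone. For the cartilage list camera gave adjusted p = 0.00027, or 0.091 with an estimated correlation. The cell division list (1 of 21 adjusted over the list alone) and the tailbud list (2 of 16) were lower. So was the hedgehog list (3 lower and 1 higher of 11). Camera adjusted p was 0.00059, 0.046 and 0.022 in this order, and 0.058, 0.2 and 0.12 with an estimated correlation. The red blood cell list (2 of 6, 0.00059, adjusted p = 0.2 with an estimated correlation) and the muscle list (1 of 19, 0.042, adjusted p = 0.14 with an estimated correlation) were higher, with no member past the gene test over all genes. The smooth muscle list did not pass (camera adjusted p = 0.083). In all, 85 genes passed, 43 higher and 42 lower. The count was 6 and 16 without hemipenis stage 9 replicate 1 and 2, 51 and 42 without stage 5 replicate 1 and 2, 10 and 27 without hindlimb stage 3 replicate 1 and 2, and 5 and 7 without hindlimb stage 5 replicate 1 and 2. STMN3, CCDC85A and ALX1 were the named genes past the threshold under every setting run.

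Across genes, genital and hindlimb changes with stage had a Pearson correlation of 0.249 and a Spearman correlation of 0.307 in the mouse (14510 genes). They were 0.0195 and −0.115 in the anole (16467 genes). The stages again differed. Over the genes past the test in at least 1 of the time contrasts, such as KRT5 in the mouse and HOXB9 in the anole, the Pearson values were 0.49 (273 genes) and 0.354 (263 genes). Without genital tubercle E11.5 replicate 2 the mouse value was 0.122, and without hindlimb stage 3 replicate 1 the anole value was −0.000536.

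The last comparison set forelimb against hindlimb buds. In the mouse, TBX5 was at 324 ± 10.3 CPM in the forelimb and 3.3 CPM in the hindlimb, a 98.1-fold difference (adjusted p = 0.0076). TBX4 was at 0.92 ± 0.437 against 97.6 CPM, PITX1 at 0.0512 ± 0.0724 against 119 CPM and HOXC10 at 1.14 ± 0.457 against 120 CPM (adjusted p = 0.015, 0.015 and 0.0015). TNC (93.6 ± 40 against 8.74 CPM), ALCAM (171 ± 42.3 against 20.9 CPM), TIPARP and GDI2 were also higher in the forelimb. HOXD12 (0.122 ± 0.173 against 13.3 CPM), SYNPO2 and the macrophage receptor MRC1 (0.163 ± 0.0585 against 10.3 CPM) were lower. ISL1 was at 1.21 ± 1.57 against 59.2 CPM and HOXA13 at 0.154 ± 0.217 against 9.13 CPM (adjusted p = 0.051 for each). The macrophage list was lower with 1 of 11 past the test and 7 adjusted over the list alone (camera adjusted p = 7.9e-08, adjusted p = 0.05 with an estimated correlation). Posterior HoxA and HoxD genes were lower with HOXD12 and HOXA10 (12.4 ± 2.32 against 65.3 CPM) past the test among 10, and 7 lower and 2 higher adjusted over the list alone. Camera on HoxA and HoxD genes gave adjusted p = 5.3e-06, or 0.067 with an estimated correlation. The limb identity list was lower, with TBX5 higher and PITX1 and TBX4 lower among 5, or 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation). So was the smooth muscle list, with SYNPO2 past the test among 10, and 2 adjusted over the list alone (0.0061, adjusted p = 0.33 with an estimated correlation). The red blood cell list was higher with 0 of 16 in either count (0.0037, adjusted p = 0.64 with an estimated correlation). The hedgehog, surface epithelium and sex-linked lists did not pass (camera adjusted p = 0.11, 0.11 and 0.12). In all, 31 genes passed, 8 higher and 23 lower in the forelimb, and 3160 had an unadjusted p under 0.05. With the 12 libraries counted separately 1935 were higher and 1860 lower, with DESeq2's Wald test 1438 passed, and without forelimb replicate 1 or 2 edgeR called 0 or 3, so that every named call ended without at least 1 library.

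In the anole, TBX5 was at 120 ± 30.5 CPM in the forelimb and 0.625 ± 0.00875 CPM in the hindlimb on its row with more counts, a 189-fold difference (adjusted p = 0.011). TBX4 was at 3.27 ± 2.51 against 56 ± 4.24 CPM and ISL1 at 0.287 ± 0.405 against 25 ± 0.0188 CPM, and PITX1 had no count against 3.27 ± 1.65 CPM (adjusted p = 0.022, 0.0064 and 0.026). HOXC11 had no count in the forelimb, at least 70.1-fold lower. HOXB9 was at 2.78 ± 0.768 against 94.7 ± 6.48 CPM (adjusted p = 0.00018 for each). EYA4 was at 28.8 ± 1.02 against 1.4 ± 0.201 CPM (adjusted p = 0.0012). KERA, TPH1 (28.7 ± 27.7 CPM), OPCML, NEFM (45.8 ± 39.1 CPM) and CLVS2 were also higher in the forelimb. The liver protein genes AHSG (0.492 ± 0.209 against 82.9 ± 96.8 CPM) and FETUB (0 against 25.7 ± 26.9 CPM), C1QTNF7 and the vascular connexin GJA5 were lower.

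Posterior HoxB and HoxC genes were lower in 3 of 9 cases, HOXC10 (14.7 ± 8.18 against 84.3 ± 16.1 CPM) being the third, also 3 adjusted over the list alone (camera adjusted p = 0.00043, adjusted p = 0.074 with an estimated correlation). Limb identity genes were lower in 3 of 4 cases, ISL1, TBX4 and PITX1, TBX5 being left out of the anole list as it lies on 2 rows, also 3 adjusted over the list alone (camera adjusted p = 0.00059, adjusted p = 0.058 with an estimated correlation). Posterior HoxA and HoxD genes were lower with HOXD12 at 0.545 ± 0.285 against 5.44 ± 3.17 CPM, 1 of 8, and 6 adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.33 with an estimated correlation). The cell division, smooth muscle, red blood cell, endoderm and hedgehog lists did not pass (camera adjusted p = 0.099, 0.21, 0.27, 0.36 and 0.36), although PCNA (156 ± 44.1 against 497 ± 12 CPM), SMTN (2.19 ± 0.669 against 22.2 ± 3.92 CPM), CLDN4 (0.889 ± 0.202 against 8.98 ± 3.78 CPM) and the hedgehog coreceptor GAS1 (0.984 ± 0.418 against 24.1 ± 0.583 CPM) passed the gene test. In all, 1522 genes passed, 682 higher and 840 lower in the forelimb. The count was 389 and 949 without forelimb replicate 1 and 2 and 86 and 147 without hindlimb replicate 1 and 2, and EYA4, HOXC11, ISL1 and HOXB9 were the 4 of 30 named genes past the threshold under every setting run.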

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

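The tests without anole forelimb replicate 2 or hemipenis stage 5 replicate 2 were chosen after the results were seen. So were those on sex-linked and endoderm genes and TBX15 as the hindlimb marker, but not that on shared axis genes. Tests of a difference between groups were passed by 79 genes in the species interaction, by the axis difference of 0.1 and the similarity difference of 0.0247 between species, and by 5 mouse and 85 anole genes in the change with stage by tissue.

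Genital libraries lay nearer the limb end in the anole than in the mouse. Stage 5 hemipenis lay beyond stage 5 hindlimb, so the axis does not rank likeness to limb. Limb and tailbud genes were not tested apart. Against different genes as the cause, 176 genes of both axes with the same direction gave a difference of 0.139 (exact p = 0.0286). The 29 with opposite directions were left out. Without hemipenis stage 5 replicate 2 the difference was 0.0759 (exact p = 0.0286). The other hemipenis libraries lay above all mouse genital ones, so this cannot decide on limb tissue in that library. Without anole forelimb replicate 2 the difference was 0.025 (exact p = 0.229), so the limb reference may carry much of it. A difference between the species stays open too.

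The mouse time-by-tissue calls were XIST, KDM5D, UTY, DDX3Y and COL14A1, 4 of 5 on the sex-linked list. The summed CPM of Y-linked genes was at most 2.58 in the E13.0 libraries and 201 to 342 in the other mouse libraries, and XIST was at 5270 to 5790 CPM at E13.0, consistent with female embryos at E13.0. Leaving out the sex-linked list gave 263 calls over time against 272, but so short a list fixes that outcome. Sex and stage go together here, so they cannot be told apart for the other changes.

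The stage 5 hemipenis replicates differed, with TBX15 at 2.61 and 125 CPM, PAX3 at 0 and 25.9 CPM, and TBX20 at 56.3 and 2.92 CPM. The stage 9 hemipenis itself held TBX15 at 80 and 63.7 CPM, PAX3 at 43.7 and 30.9 CPM and TBX20 at 1.86 and 0.117 CPM. These genes alone thus cannot tell hindlimb tissue from hemipenis, and a stage difference between replicates was not tested. LMX1B was at 0.848 and 9.01 CPM in the replicates, 28.5 and 32.5 CPM in hindlimb and 0.931 and 0.703 CPM at stage 9. This 1 gene goes with hindlimb tissue in replicate 2. TBX15's excess over replicate 1 would put hindlimb tissue at 40%. Of 37 hindlimb genes 23 reached 0.5 of this in replicate 2 and 14 (37.8%) did not. Replicate 1 was not subtracted for these (median 29.5% of hindlimb level, 16.2% in replicate 1), so the test cannot decide. FGF8 had no count, which argues against tissue with the ridge. Endoderm genes had a median log2 ratio of 1.06 in replicate 1 over replicate 2, with 6 of 10 higher, which cannot decide whether more endoderm was taken.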

How the results depend on the processing

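The gene length offset, leaving out sex-linked genes and the settings for genes called in both species were chosen after the data were seen, and so was summing the near-identical mouse pairs in place of the planned 12 libraries. Values that changed with a setting follow, and the cause was not tested. In the mouse, counts are for genital against hindlimb, genital against tailbud, hindlimb against tailbud, genital over time, hindlimb over time, forelimb against hindlimb and time by tissue, in this order unless named. With the 12 libraries counted separately they were 1871, 2637, 2964, 1497, 1235, 3795 and 241. With the DESeq2 Wald test they were 588, 2021, 1304, 913, 193, 1438 and 85. With no filter they were 465 for genital against hindlimb, then 1249, 767, 162, 1393 and 99 from hindlimb against tailbud on. With a minimum log2 fold of 1 they were 46, 595, 312, 63, 1 and 7 for the first 6. With only the groups compared they were 2407 for hindlimb against tailbud, 109 for genital over time, 3079 for forelimb against hindlimb and 2 for time by tissue, and hindlimb over time was not run, as it sets 1 sample against 1. With a replicate block they were 61 for genital against hindlimb, 95 for genital over time, 8 for forelimb against hindlimb and 0 for hindlimb over time. Hindlimb over time gave 3 thinned to the smallest library and 0 with a gene length offset in edgeR, against 1016 at an unadjusted p under 0.05 and 193 with DESeq2. Time by tissue gave 1 leaving out sex-linked list genes. Against the earlier hindlimb the log2 fold change was −0.556 for GATA6 and 0.613 for XIST.

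In the anole, the DESeq2 Wald test gave 778 for genital against hindlimb, 810 for genital over time, 433 for hindlimb over time, 2809 for forelimb against hindlimb and 918 for time by tissue. A minimum log2 fold of 1 gave 37, 631, 437, 84, 1, 37 and 19 in the order above. With only the groups compared edgeR gave 0, 624, 1327, 151, 0, 702 and 245, where the comparisons at 0 have 2096 and 1866 genes at an unadjusted p under 0.05 in the fit of all groups. With no filter hindlimb over time gave 31 and time by tissue 183. Hindlimb over time gave 5 with DESeq2 size factors, 3 with a replicate block and 3 with a gene length offset. Size factors moved log2 fold changes by at most 0.072 in either species.

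The mouse axis position was 0.818 with the top 500 genes, 0.776 with all tested genes, 0.823 with hindlimb only and 0.783 with symbol-matched genes. The axis difference was 0.0468 with hindlimb only. The similarity difference was −0.0334 over the 1000 most variable genes and 0.00467 against the later hindlimb. The species interaction gave 275 with separate fits, 26 with a minimum log2 difference of 1 and 444 with the 12 libraries. Genes called in both species numbered 22 against the earlier hindlimb and 41 with the 12 libraries. The correlation between species was 0.416 over genes past 0.05 and 0.283 over those of at least 5 CPM. The time correlations were 0.49 and 0.366 in the mouse and 0.354 and −0.0226 in the anole. List calls numbered 14 in the mouse and 6 in the anole with an estimated correlation, against 61 and 57.

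Leaving out 1 library at a time gave ranges in the same order of 151 to 228, 576 to 1267, 259 to 617, 72 to 340, 6 to 7, 0 to 31 and 5 to 19 in the mouse, and 37 to 109, 1153 to 1452, 818 to 1471, 78 to 177, 1 to 4, 86 to 949 and 5 to 51 in the anole. Leaving out a mouse hindlimb library took away only part of a near-identical pair, so the 6 to 7 for mouse hindlimb over time says nothing of its stability. The 0 came from edgeR without mouse forelimb replicate 1, with 3160 at an unadjusted p under 0.05 and 1438 by DESeq2 in the fit with it. Axis positions ran from 0.785 to 0.836 in the mouse and 0.823 to 0.907 in the anole, and their difference from 0.025 to 0.113. Similarity ran from 0.0195 to 0.0293, the interaction from 29 to 119, genes called in both species from 3 to 11, and the correlation between species from 0.0734 to 0.169. The time correlations ran from 0.122 to 0.293 in the mouse and −0.000536 to 0.046 in the anole. Of 453 named-gene results 340 passed, and 157 passed under every setting run. Leaving out 1 library weakened 443 of 2032 gene and library combinations and strengthened 16.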

Other observations

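The tests without single libraries were chosen after the results were seen. ZEB2, SVEP1, RDH10 and ZIC2 passed in both species, in the same direction, between genital tissue and hindlimb at the shared stage, and of these ZIC2 alone did so without any 1 library. ZEB2, a zinc finger repressor, was at 89.8 ± 2.9 against 16.1 CPM in the mouse and 110 ± 22.4 against 32.5 ± 3.25 CPM in the anole. SVEP1, an extracellular adhesion protein, was at 30.7 ± 3.75 against 4.83 CPM and 161 ± 33 against 35.2 ± 5.14 CPM. ZIC2 was at 0.0723 ± 0.102 against 6.9 CPM and 0.743 ± 0.129 against 14.6 ± 3.89 CPM.

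Relative to gene means, log counts had Spearman correlations with gene length of −0.203 and −0.198 in mouse E10.0 hindlimb. They were −0.209 and −0.151 in anole stage 3 hindlimb and −0.104 to 0.2 elsewhere.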
